A study of Mus musculus with 4 samples.

How the data were processed

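Cap analysis of gene expression (CAGE) sequences short tags that start at the capped 5' end of an RNA, so a tag marks a transcription start and its number does not depend on transcript length. The samples were 4 libraries of lesional facial skin from mice that carry the FADS model (a facial atopic dermatitis model in which Ikk2, encoded by Ikbkb, is deleted by a Cre recombinase) and lack Postn, which encodes the matrix protein periostin. The labels place all 4 in 1 group, of C57BL/6 mice at 28 days of age. They do not say what the sample codes mean or whether the skins came from 4 animals, so p-values measure only the spread between these samples, which may be technical. With 1 group, no comparison between genotypes or treatments was made.

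Per the labels' protocols, total RNA was purified on columns and CAGE libraries were made with a commercial kit. BWA and HISAT2 are named, with no version given here, in the submitters' processing notes, which also name the mm9 build. The coordinates fit another build: 99.9% of the clusters that carry a gene name lay within 1000 bp of that gene in GENCODE M21 on GRCm38, and 17828 of 17849 gene identifiers were found there. Positions are therefore given on GRCm38, as deposited, with the start uncertain by 1 bp. The step that joined tags into clusters is not given in the sources used here.

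The deposited table held CPM, the tags of a feature scaled to a common library total, for 69391 entries, each a cluster of tag starts with a gene name or none. The authors' CPM were whole multiples of the value of 1 tag in 100% of values (tolerance 0.02 tags), so whole tags were recovered. The totals over all entries, to which the CPM refer, were 18179860, 18823630, 17630119 and 17939565 tags for libraries 1 to 4, and 1 tag was worth 0.0550, 0.0531, 0.0567 and 0.0557 CPM. Of the entries, 2072 repeat a cluster for another gene, so its tags count again in these totals; distinct clusters held 17026618, 17691558, 16492915 and 16787072 tags. No tag in any library was held by 1072 entries. The 67319 distinct clusters include 20326 with no gene name, which took 11.0%, 9.67%, 10.2% and 9.69% of their tags; these entered the totals and no test. Tags were summed per gene. Each cluster listed under several genes was assigned first to 1 of them, a gene with a given name before a predicted, small RNA or clone name, and then the gene with more tags. Of 17849 genes, 33 had no tag, 779 with at least 90% of their tags in clusters assigned to another gene were set aside, and 17037 were kept. A kept gene retained all tags of its clusters, shared ones included: 495 kept genes had at least 90% of their tags in clusters listed under another gene too, and the table does not show which gene gave rise to these tags. They include Neat1, Rps2 and Col3a1, the list members Cd3e, Il2rg, Itgam, Trps1 and Col1a2, and Esp6 and Krtap22-2. Families of near-identical genes (Krtap, Scgb, Sprr, Krt6a and Krt6b) can share tags in ways the table does not show, and their levels are uncertain to that extent. A gene counted as detected with at least 3 tags, 0.159 to 0.170 CPM. Intervals and floors cover counting error only.

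Levels are CPM with the SD over 4 libraries. The test of spread asks whether a gene differs between the 4 libraries more than genes of its level do. It used log2(CPM + 1) with TMM scaling (factors 0.997, 0.924, 1.04 and 1.04), genes of at least 1 CPM on average, and in limma 3.58.1 a robust prior trended on level (3.61 prior degrees of freedom), with a one-sided upper F test and Benjamini-Hochberg adjustment at 0.05. The design fixed before the data were examined named edgeR on counts; the deposited unit is CPM, so limma took its place, and edgeR 4.0.16 on the recovered tags and DESeq2 1.42.0 were alternatives. Ranges on the log2(CPM + 1) scale understate those of low genes. For each of 28 gene lists, the median deviation of its members from their means was taken per library, and its range over the 4 libraries was ranked among 10000 random lists of the same size and level; the smallest p this can give is 0.0001. Random lists take genes as independent, which genes of 1 cell type are not, so this ranks the libraries at hand only. For 32 gene pairs, log2 ratios within each library (0.5 tags added) were tested against 0 with limma, two-sided. All tests take the 4 libraries as independent. Libraries that share a part of the sample code may not be, and p-values are then too small. Those that share the first part did resemble each other more than the rest, with a root mean square log2 difference of 0.24 against 0.35 to 0.38. Genes that passed the test of spread were left out of these differences. Lists, pairs and most alternatives were fixed before the data were examined.

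Each test was run on simulated data. The spread test was simulated under 8 assumed distributions of gene variability, with 50 genes changed at each fold; all 8 are reported because the outcome depended on the choice and the distribution was varied after results had been seen. On 14804 to 14836 genes per setting it recovered 49 or more of 50 genes changed 64-fold, 17 or more of 50 changed 16-fold, from 0 to 50 of those changed 4-fold and from 0 to 32 of those changed 2-fold. False calls numbered 7 to 41 and made up 6.71% to 23.3% of the calls, above the nominal 5% in each setting. The measured median SD of log2 values, 0.125, was closest to the setting with 0.127, which gave 41 false calls, 23.3%. By the upper quartile, 0.203, the closest setting had 0.196, with 9.68% false. With fewer changed genes than simulated, the share could be larger. The list test called 10 of 10 lists moved 2-fold in 1 library and 0 of 10 that were not moved. Simulated genes varied independently, so false calls for lists of genes that vary together were not measured. The pair test called 10 of 10 pairs at a true log2 ratio of 0.5 and 0 of 10 at 0. All simulated pairs had the same SD, whereas the measured SD of the log2 ratio ran from 0.06 to 1.26. The pair simulation therefore does not cover the more variable pairs.

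The genes named were chosen by a rule set beforehand: the 20 with the highest mean CPM, up to 4 of each list by level, up to 20 with the smallest adjusted p for spread, the genes of the pairs, and Postn, Ikbkb and Nes, 168 in all. Others named were chosen after their values were seen. Members of lists with no entry in the table were not analysed here; 353 of 416 were analysed. The results of 2 genes are not reported here and were left out of the search for libraries that stand apart. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9 and R 4.3.3.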

Results

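Capped 5' ends of RNA were counted in 4 libraries of lesional facial skin from Postn-null mice with the FADS form of dermatitis. All libraries belong to 1 group, so each level is given with the spread over the 4 libraries, and differences are those between genes, between gene lists or between single libraries. The deposited entries summed to 18179860, 18823630, 17630119 and 17939565 tags, which count a cluster again for each gene it is listed under; distinct clusters held 17026618, 17691558, 16492915 and 16787072. At least 3 tags were found for 16306, 16365, 16380 and 16393 genes, and 15876 genes reached this in every library. Of the tags in clusters with a gene name, 95.5% lay within 500 bp of an annotated start of that gene.

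The question of the genotype comes before the others. Postn held 15, 6, 10 and 7 tags, 0.525 ± 0.226 CPM (SD, n = 4), rank 15446 by level. Its tags lay in 1 of 3 clusters, on chromosome 3 from 54361096 to 54361141 on the plus strand, which spans an annotated transcript start (ENSMUSG00000027750.16). The labels do not say which part of the gene was removed, so tags at its 5' end are no measure of the allele. Tgfbi, a matrix protein related to periostin, stood at 81.5 ± 22.9 CPM, and the ratio of Postn to Tgfbi was 0.00657 (log2 -7.25 ± 0.63 SD, n = 4, limma adjusted p = 6.48e-06). With no library that keeps Postn, this ratio is no test of the genotype. Ikbkb, the floxed kinase gene, stood at 36.2 ± 2.06 CPM, close to Chuk, which encodes the partner kinase, at 35.6 ± 1.96 CPM; their log2 ratio of 0.03 ± 0.08 did not pass (limma adjusted p = 0.71). A 5' tag does not show whether exons further down were removed. Nes, the nestin gene, stood at 7.11 ± 0.798 CPM; the labels spell the promoter of the Cre transgene as Nectin, and whether Nes is meant was not settled here. Xist, transcribed from the inactive X chromosome, was at 240, 214, 293 and 290 CPM, while the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty held at most 2 tags in any library.

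Among entries with a gene name, the most abundant RNAs were nuclear noncoding transcripts, epidermal differentiation genes and, in some libraries, transcripts of secreted proteins. Malat1 led with 11730 ± 287 CPM and Neat1 followed with 4641 ± 248 CPM; 4 single clusters with no gene name, at 5520 to 8688 CPM, stood between them. Krt10 and Krt1, keratins of the suprabasal epidermis, stood at 3476 ± 808 and 2642 ± 595 CPM, and Lgals7 at 3220 ± 210.0 CPM. Fabp5 (2923 ± 473), Dmkn (2826 ± 523), Actb (2683 ± 167), Apoe (2419 ± 34.0), Cstdc5 (2274 ± 469) and H4c4 (2220 ± 121) came next, with Krt71, a keratin of the inner root sheath of the hair, at 2218 ± 642 CPM. The collagen genes Col1a1 (2102 ± 574) and Col3a1 (2010 ± 709) stood near Rps2 (2026 ± 104), Scarna2 (1999 ± 303) and S100a6 (1931 ± 173). Nearly all tags of Neat1, Rps2 and Col3a1 (99.7% for Col3a1) lay in clusters that are also listed under another gene, among them Gm27505, Snora64 and Gm47302. Bpifa2, Gm1553 and Mucl2 ranked among the 20 highest by their mean because of 1 or 2 libraries.

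Genes of the fixed keratinocyte lists were abundant. There is no healthy skin here, so their levels do not show whether the lesion raised them. The 20 analysed members of the stress and hyperproliferative list summed to 8867 ± 1690 CPM, led by Sprr1a (1524 ± 173), Krt6b (1377 ± 342), Sprr1b (1271 ± 358) and Krt17 (1232 ± 118). The suprabasal list summed to 12740 ± 2230 CPM, the cornified envelope list to 3531 ± 437 and the basal list to 2735 ± 457. Their member medians of 173, 701, 123 and 212 CPM lay above those of all 10000 random lists of the same size. Krt10 exceeded the basal keratin Krt14 by 4.71-fold (log2 2.24 ± 0.34, adjusted p = 5.66e-05), and Flg, the filaggrin gene, exceeded Lor, the loricrin gene, by 3.36-fold (log2 1.75 ± 0.10, adjusted p = 1.02e-05). Sprr1b exceeded Lor 9.92-fold, and Krt6a stood at 0.579 of Krt6b.

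Genes of the type 2 response, which interleukins 4 and 13 induce, were led by Chil4, a chitinase-like protein, at 1734 ± 306 CPM. The chemokine gene Ccl8 stood at 286 ± 91.0, Retnla at 187 ± 46.1 and Arg1 at 133 ± 37.2 CPM. Il4, Il5, Il13 and Il31 were not analysed here. The alarmin gene Il33 stood at 49.7 ± 20.9 CPM and exceeded Tslp, at 2.09 ± 0.685 CPM, by 23.1-fold in 4 of 4 libraries (log2 4.53 ± 0.24, adjusted p = 2.5e-06). The receptor genes Il4ra (98.0 ± 19.0) and Il13ra1 (80.9 ± 18.5) did not pass as different (log2 -0.29 ± 0.26, adjusted p = 0.0687), and the decoy receptor gene Il13ra2 stood at 0.0418 of Il13ra1, or 0.0256 with the most used cluster of each gene alone. Jak1 exceeded Jak3 22.0-fold, and Stat6 stood at 0.482 of Stat3. Among the integrins that can bind periostin, Itgb1 (179 ± 19.9) exceeded Itgb3 (12.5 ± 1.83) by 14.3-fold (log2 3.84 ± 0.06, adjusted p = 1.14e-06), and Itgb3 stood at 0.147 of Itgb5.

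**Figure D1:**
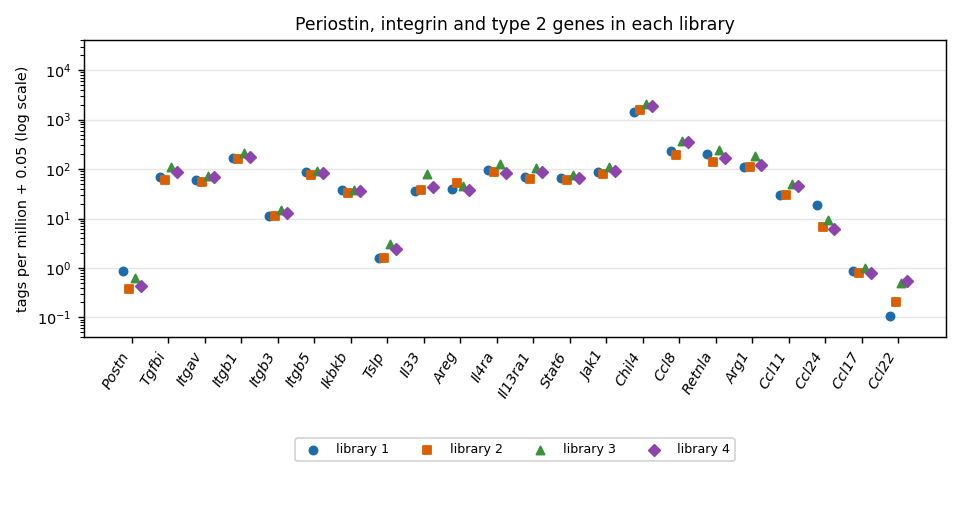
CPM, plus 0.05, on a log axis for periostin, integrin and type 2 genes; each symbol is 1 of the 4 libraries. Postn lies between 0.32 and 0.83 CPM, and Chil4 between 1399 and 2075 CPM.

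Of 32 fixed pairs, 28 had both genes and 24 had a ratio different from 1 (limma, adjusted p under 0.05), each of these in 1 direction in 4 of 4 libraries. Those that did not pass were Il13ra1 over Il4ra, Krt16 over Krt17, Col1a1 over Col3a1 and Ikbkb over Chuk. Single libraries decided 3 pairs: Il13ra1 over Il4ra passed without library 4 (log2 -0.40), Krt16 over Krt17 passed without library 3 (log2 -0.30), and Ccl17 over Ccl22 no longer passed without library 2 (log2 1.64). An exact sign-flip test called 0 pairs, since its smallest two-sided p comes from 2 of the 16 sign patterns of 4 libraries. With the mean of the libraries that share the first part of the sample code, 22 pairs passed, without Ccl17 over Ccl22 and Krt1 over Krt10 (limma adjusted p = 0.0501 for both). The limma adjusted p with these means was 0.000236 for both Itgb1 over Itgb3 and Postn over Tgfbi. It was 1.14e-06 and 6.48e-06 with the 4 libraries taken singly.

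Immune cell genes were low beside those of the epidermis. The macrophage list summed to 198 ± 19.5 CPM, the mast cell and basophil list to 78.8 ± 6.94, the neutrophil list to 28.5 ± 7.18, the eosinophil list to 9.36 ± 3.33 and the B and plasma cell list to 3.0 ± 0.891. Sums cover analysed members only: 8 of 13 neutrophil, 3 of 9 eosinophil, 3 of 11 B and plasma cell and 9 of 18 T cell symbols. They can therefore understate these cells. The T cell list summed to 323 ± 22.9 CPM, of which Gata3, a transcription factor that keratinocytes express too, made up 306 ± 20.7; Cd3g stood at 4.44 ± 1.77 CPM. The dendritic and Langerhans list summed to 604 ± 119 CPM, led by Cd74 (205 ± 52.7) and Epcam (176 ± 20.7). The skeletal muscle list, at 5424 ± 2050 CPM, and the fibroblast and matrix list, at 5474 ± 1620, were far above these. The type 1 and type 17 list summed to 111 ± 12.3, the interferon-stimulated list to 110 ± 23.7, the NF-kB list to 470 ± 59.8 and the itch list to 207 ± 11.5 CPM.

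Transcripts of secreted proteins, secretoglobins among them, were far higher in library 2 than in libraries 1 and 3, and most of them were also high in library 4. The sample codes of libraries 2 and 4 end in R and those of 1 and 3 in L, and the labels do not say what these letters mean. Mucl2 stood at 1.93, 9099, 0 and 3369 CPM in libraries 1 to 4, Gm1553 at 1.65, 8971, 0 and 4013, and Obp1a, an odorant-binding protein, at 0.55, 3142, 0 and 1327 (limma adjusted p = 0.002 for each). Bpifa2, a salivary protein gene whose cluster spans an annotated start on chromosome 2 from 154008263 to 154008267 on the plus strand, stood at 4.18, 16004, 0.113 and 4.46 CPM, and Smr3a at 0.825, 3484, 0 and 0.557. In all, 61 of 14732 genes varied between libraries beyond the trend (limma, Benjamini-Hochberg). On simulated data of like size 7 to 41 calls were false, 6.71% to 23.3% of the calls made there. The highest share came from the setting whose median SD was closest to the measured one. The share among the 61 was not measured and can be higher. By bounds chosen after the values were seen, 30 of these were at least 5-fold higher in library 2 than in libraries 1 and 3; they took 5.83% of the tags of library 2, 1.51% of library 4, 0.00467% of library 1 and 0.00142% of library 3. All tags of Esp6 and Krtap22-2, which are among the 61, lay in clusters that are also listed under another gene. Names beginning Scgb (8 of 14 tested, adjusted p = 3.72e-14) and Esp (4 of 7, 1.45e-06) were over-represented among the 61 by Fisher's exact test over 471 name stems. Fisher's test takes genes as independent, which members of 1 family that vary together are not, so its p-values are too small.

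Hair shaft genes formed most of the other part. The remaining 31 called genes were at least 3-fold higher in library 1 than in library 4. They took 1.62%, 1.56%, 0.374% and 0.164% of the tags of libraries 1 to 4. Their limma adjusted p for spread ran from 0.0235 to 0.0456, near the 0.05 threshold, and was 0.0411 for Krtap15 and Krt34. Krtap15 stood at 2273, 2203, 621 and 209 CPM and Krt34 at 421, 393, 108 and 58.0 CPM, both named after their values were seen, as was Crisp1, a secreted protein gene among the 31 that was highest in library 2 (53.9, 156, 9.64 and 2.17 CPM). Keratin-associated proteins, which crosslink the hair keratins, were over-represented (20 of 53 tested, adjusted p = 5.79e-33), and so were keratins (5 of 46, 0.000146). These p-values of Fisher's exact test are too small for the same reason. The fixed hair follicle list held 2 genes called over all genes, 13 of 15 adjusted over the list alone, and 0 by edgeR. The test called 0 genes (limma) with libraries 1 and 3 alone, which leave 1 residual degree of freedom. There 714 of 14732 tested genes had an unadjusted p under 0.05, against 940 with all libraries. Chance gives about 1 in 20 of the tested genes, and 714 is no more than that. The hair follicle list still ranged over 1.29 with libraries 1 and 3 alone, against 1.31. The test also called 0 genes (limma) when the gland and hair families, with 48 of the 61, were left out. Then 912 of 14626 tested genes had an unadjusted p under 0.05. With at least 10 or at least 50 tags in every library the test again called 0 genes (limma). All 31 genes met the first minimum and most met the second, so they were tested there and lost their calls. The limma test called 13 without library 4 and 118 without library 3, and DESeq2 marked 513. The edgeR test, which the design had named before the data were examined, called 35, of which 34 were among the 61.

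**Figure D2:**
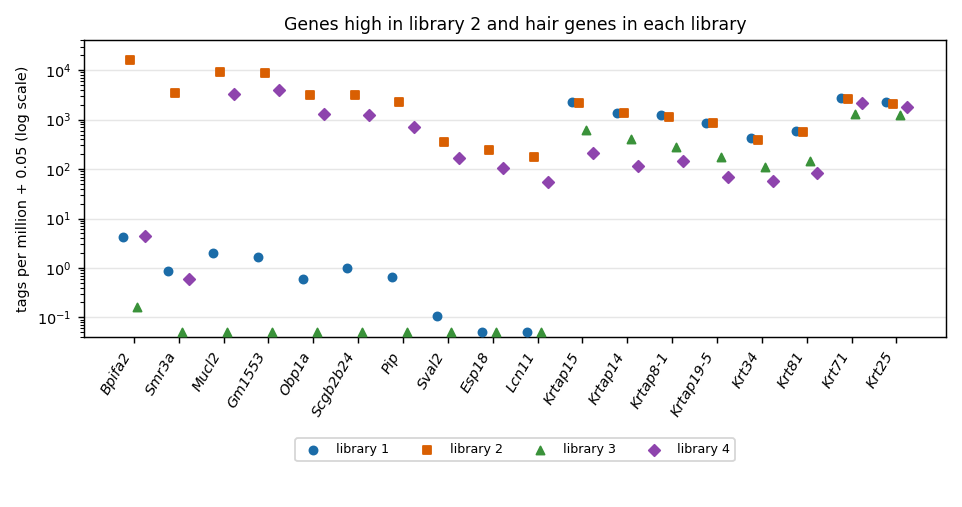
CPM, plus 0.05, on a log axis for genes high in library 2 (Bpifa2 to Lcn11) and hair genes (Krtap15 to Krt25); each symbol is 1 of the 4 libraries. Bpifa2 reaches 16004 CPM in library 2 and stays at or under 4.46 CPM in the others, and Krtap15 lies between 209 and 2273 CPM.

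In CPM without TMM scaling, skeletal muscle genes were highest in library 4 for 17 of 17 tested members. Acta1 stood at 850, 631, 1016 and 1516 CPM and Myh4 at 442, 357, 493 and 908 CPM. The list's median ranged over 1.12 on the log2 scale, above all 10000 random lists (adjusted p = 0.000357); 0 members were called over all genes by limma, 0 by edgeR, 17 at an unadjusted p under 0.05 and 17 adjusted over the list alone. The muscle list's range was 0.60 without library 4 (adjusted p = 0.000312) and 0.28 with libraries 1 and 3 alone (adjusted p = 0.00111). The hair follicle list ranged over 1.31, highest in library 1 and lowest in library 3 (adjusted p = 0.000357).

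Stress keratinocyte, matrix and type 2 genes were highest in library 3. All 18 tested members of the stress keratinocyte list, 10 of 10 basal, 16 of 19 fibroblast and matrix, 14 of 15 type 2 receptor and 7 of 10 type 2 response genes had their highest value there. These counts used CPM without TMM scaling, while the ranges below used TMM. Without TMM the median gene deviated by log2 -0.016, -0.086, 0.049 and 0.058 in libraries 1 to 4. The share of all tested genes that were highest in library 3 was not counted. Krt6b stood at 1242, 1147, 1885 and 1233 CPM, Il33 at 36.5, 38.5, 80.7 and 43.2, and Col3a1 at 1555, 1324, 2877 and 2287. The medians ranged over 0.60 for the stress list, 0.61 for fibroblast and matrix, 0.50 for basal, 0.47 for type 2 response, 0.32 for type 2 receptors and 0.59 for the 3 tested type 2 cytokine and alarmin genes (adjusted p = 0.000357, 0.000357, 0.0005, 0.000357, 0.000769 and 0.0267). Endothelial (0.56), sebaceous (0.51), dendritic (0.50), suprabasal (0.32), NF-kB (0.30) and cornified envelope (0.28) lists were also highest in library 3 and stood above random lists. Interferon-stimulated (0.43), adipocyte (0.37) and proliferation (0.18) lists were highest in library 4. In all 17 of 25 lists passed, and without library 3 only 9 did. The lists lost without it were basal (range 0.18), suprabasal (0.16), cornified envelope (0.08), type 2 response (0.18), type 2 receptors (0.09), type 2 cytokines (0.20), NF-kB (0.14) and proliferation (0.09). Among those that still passed without library 3, the stress list ranged over 0.21, fibroblast and matrix over 0.39 and sebaceous over 0.33. The sebaceous list ranged over 0.24 without library 1, and the adipocyte list over 0.19 without library 2 and 0.23 without library 4. Proliferation was also lost without library 4 (range 0.13, adjusted p = 0.108), and with libraries 1 and 3 alone proliferation (adjusted p = 0.0669) and adipocyte (0.284) did not pass. With the mean of members in place of the median, 5 lists passed: stress keratinocyte, hair follicle, sebaceous, fibroblast and matrix, and skeletal muscle. The other 12 did not, with adjusted p from 0.106 for 5 of them to 0.274 for proliferation.

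The other 8 lists did not pass. The periostin and integrin list ranged over 0.18 (adjusted p = 0.0543), macrophage over 0.21 (0.0816), Schwann and melanocyte over 0.16 (0.0834), itch over 0.21 (0.0956), T cell over 0.38 (0.097), mast cell over 0.29 (0.117), neutrophil over 0.34 (0.223) and type 1 and type 17 over 0.19 (0.327). The periostin and integrin list passed with DESeq2 size factors (0.0435), without scaling (0.0105) and without library 2 (0.0197). The T cell list passed without scaling (0.0447) and without library 1 (0.0221), and the macrophage list without scaling (0.0345), without library 1 (0.0185) and without library 4 (0.0391). The itch list passed without library 2 (0.0313) and with libraries 1 and 3 alone (0.0272). Without library 3 the ranges of lists that did not pass fell to 0.04 for itch, 0.07 for neutrophil, 0.08 for macrophage, 0.10 for periostin and integrins, 0.11 for type 1 and type 17 and 0.19 for mast cell. The itch list fell to 0.08 without library 1, T cell to 0.22 without library 2, and neutrophil to 0.22 without library 4. Of single members, 4 of 11 sebaceous, 5 of 13 Schwann and melanocyte and 1 each of the cornified, neutrophil and type 2 cytokine genes were called adjusted over the list alone, and none of these over all genes by limma. Eosinophil, B cell and sex-linked lists had too few tested members.

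**Figure D3:**
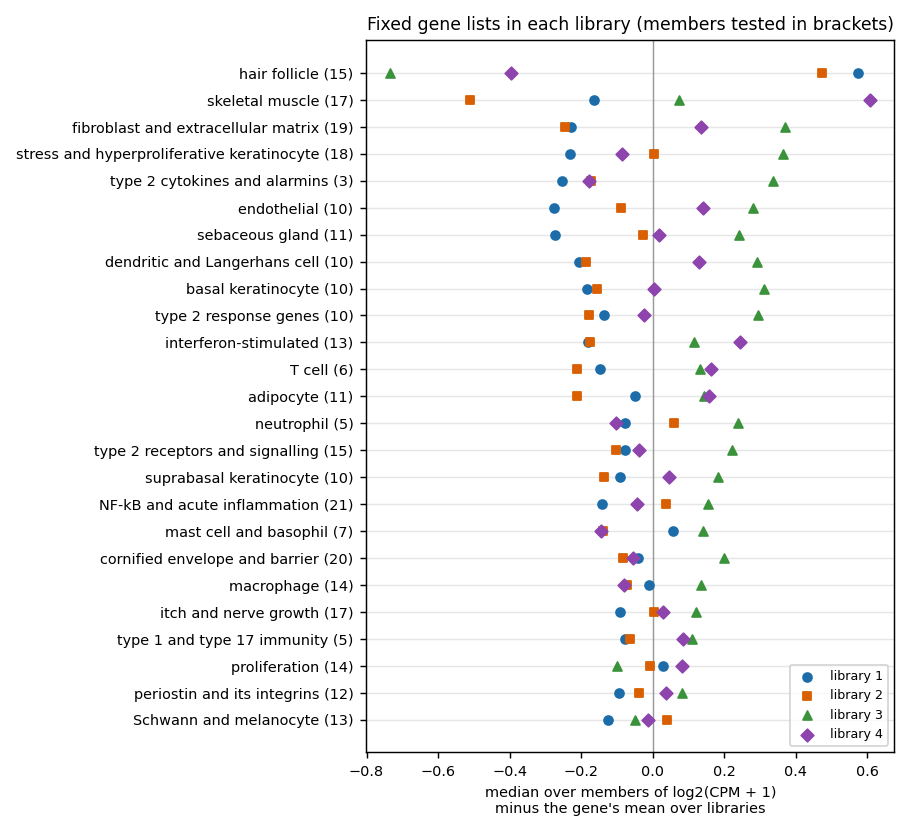
Median over the members of each fixed list of log2(CPM + 1) minus the gene's mean over libraries, with 1 symbol per library and the number of tested members in brackets. The hair follicle list spans 1.31 and the skeletal muscle list 1.12.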

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

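The tests of gland genes against a common source, of scaling, of the traces and of the hair genes were chosen after the results were seen; the test on secretory cell genes was set before their values were looked at. In 194 results with 4 libraries each (166 genes and 28 list sums), 10 had 1 library standing apart by Dixon's ratio, past its 95% critical value; chance gives about 1 in 20, and 8 of the 10 are library 3. High in library 3 were Arg1 (0.878), Fabp5 (0.905), Il33 (0.848), Krt6b (0.872), Mcpt4 (0.834), Sprr1b (0.83) and the summed stress keratinocyte list (0.959); the summed Schwann and melanocyte list was low there (0.887). Bpifa2 (1.0) and Smr3a (1.0) were high in library 2. Clusters with no gene name, which no test used, held 10.1% of tags on average (SD 0.616).

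Of the 30 called genes that are high in library 2, 27 were in a ratio of 0.258 to 0.637 between libraries 4 and 2, a 2.47-fold span. The bound on this span was set after the values were seen and took no account of counting error. It could not decide on 1 source of gland RNA shared by both libraries, which stays open for the 27. Car6 (ratio 0.103) was left out of these, since it was no higher in library 4 than in library 1 (21.9, 181, 4.37 and 18.7 CPM). For Bpifa2 and Smr3a such a shared source is excluded: the median ratio of the 30 genes was 1435 times the higher of these 2 genes' ratios. Scaling is excluded, since the median log2 range was 8.0 with TMM and 7.87 without scaling. Gland cells in the sampled tissue may be a candidate source. A list of 12 measured secretory cell genes not looked at before had its range at percentile 92.8 of random lists. Library 2 was no higher than 3 or 4 in it. Several of these genes are skin genes too (Cldn4 at 198, 182, 157 and 143 CPM), so the list could not decide for or against gland cells, which stay open. A list of 23 gland genes looked at earlier ranged over 1.06 and was highest in libraries 2 and 4 (medians -0.41, 0.65, -0.35 and 0.21). Its member Bhlha15 stood at 0, 22.0, 0 and 6.19 CPM. Members differed: Krt7, Krt19, Slc12a2, Xbp1 and Egf were highest in library 3 and Elf5 in library 1. Kcnn4, Chrm3 and Wfdc12 were lower in library 4 than in library 1. The list's values were known when it was written, and 1 of its genes is a called gene.

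Library 1 held traces of these transcripts. Over 20 genes with at least 100 CPM in library 2 and, by choice, under 3 tags in library 3, library 1 held 2.18 tags per 10000 of library 2 (exact Poisson interval 1.91 to 2.48); Bpifa2 and Smr3a in library 4 stood at 2.66 and 1.52 per 10000. Carry-over of tags from library 2 may explain this: the traces stood in 1 ratio within counting error, with an index of dispersion of 1.32 against a chance limit of 1.59. Gland cells in that skin cannot be told apart from it, since only 0.09 tags of Bhlha15 would be predicted.

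The hair shaft genes are not accounted for by a lower share of follicle RNA alone: between libraries 1 and 4 the median log2 difference of 53 keratin-associated proteins exceeded that of 7 inner root sheath keratins by 2.03 (2.52, quartiles 1.85 and 3.13, against 0.50, quartiles 0.41 and 0.90). Between libraries 1 and 3 the gap was smaller, 0.69 (1.81, quartiles 1.47 and 2.21, against 1.12, quartiles 1.02 and 1.27), so a lower share in library 3 could account for part of the difference there. Scaling is excluded as well, with a median range of 2.64 under TMM and 2.47 without it. The stage of the hair cycle or the site sampled could differ between skins and stays open: the design gives 1 group, so a difference between animals or sites was not tested for any of the 3 patterns, and gland and follicle RNA were tested only as a mixture of tissues.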

How the results depend on the processing

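Some alternatives were chosen after seeing the data. These were fewer libraries than 3, a minimum of 10 tags, the gene-assigned total and means over a part of the sample code. Leaving out gland and hair families, or genes with shared tags, was also chosen then. For the test of spread, edgeR was the test named in the design before the data were examined, and limma took its place. The 61 genes with more spread became 104 without scaling and 513 as DESeq2 dispersion outliers, both holding all 61, and 35 by edgeR on recovered tags (34 shared), 11 with a prior that is not robust, and from 13 (without library 4) to 118 (without library 3) with 1 library left out. It was 58 without genes that share at least 90% of their tags, all 58 among the 61. The count was 0 (limma) with at least 50 tags in every library, 0 with at least 10 tags in every library, 0 with libraries 1 and 3 alone and 0 without the gland and hair families, which removed 106 genes and 48 of the 61; 781, 936, 714 and 912 genes in this order had an unadjusted p under 0.05. A minimum in every library removes genes absent from some by construction. This does not account for the 31 called genes that were higher in library 1 than in library 4. Each of them held at least 29 tags in every library and most held at least 50, so they stayed in the test but were not called. Libraries 1 and 3 alone leave 1 residual degree of freedom. For the 31 genes and for the other settings the cause was not tested. The 17 lists became 5 with the mean of members, and 9 to 19 with 1 library left out, 9 being without library 3; the cause was not tested. The 24 pairs became 0 under the exact sign-flip test, which cannot reach the threshold with 4 libraries, and 22 and 24 with means over libraries that share the first or the second part of the sample code. The count of genes detected in every library, 15876, lay between 14909 and 16473 under the alternatives run. Of 1372 alternatives for 196 levels, 1318 moved by less than 1 SD and 54 by more, 36 of these with the gene-assigned total. Leaving out 1 of 4 libraries cannot move a mean by 1 SD. The alternatives that did so counted among the 1318 by construction and are no evidence of stability. Of 224 for 28 pair ratios, 219 stayed on their side of the threshold, 5 did not and none of the 24 called pairs reversed; Ikbkb over Chuk, which was not called, turned to log2 -0.00198 without library 1. No paired comparison was run, since there is 1 group and no groups were made from sample codes of unknown meaning.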

Other observations

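Pigment genes of the hair, a list of 7 chosen after values were seen, had median deviations that ranged over 0.89 on the log2(CPM + 1) scale. The fixed Schwann and melanocyte list, which holds 5 of the 7, did not pass (range 0.16, adjusted p = 0.0834). Tyr stood at 31.9, 28.5, 17.8 and 20.5 CPM in libraries 1 to 4, Pmel at 33.0, 28.5, 16.7 and 20.2, and Oca2 at 11.9, 9.24, 4.82 and 5.41; none of these 3 genes passed the test of spread alone. All 7 of 7 had a higher value in library 1 than in library 4, with a median log2 difference of 0.81.

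Libraries 1 and 2 resembled each other, as did 3 and 4, once the 61 called genes were left out: the root mean square log2 difference was 0.24 for each of these pairs and 0.35 to 0.38 for the other 4. Over 14304 genes outside the called genes, the keratin names and the fixed lists, the pairing of 1 with 2 and 3 with 4 left the smallest differences for 53.8%, against 23.4% and 22.7% for the other pairings. Of the 61 called genes, 33 differed least under the pairing of 1 with 2 and 3 with 4, 28 under that of 1 with 3 and 2 with 4, and 0 under that of 1 with 4 and 2 with 3. Libraries 1 and 2 share the first part of their sample codes, and so do 3 and 4; libraries 1 and 3 share the last letter, L, and 2 and 4 the letter R. The labels give the meaning of neither part.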
